A study of Mus musculus with 32 samples.

How the data were processed

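Gene expression was measured on 2-colour arrays in liver and spleen of mice made by somatic nuclear transfer. The 32 arrays fell into 4 groups of 8: mice carrying a Dll1 mutation and wildtype mice, in each of 2 organs. Each group held 4 male mice of 1 inbred strain, aged 18 to 19 weeks, and each mouse was hybridised on 2 arrays with the dyes swapped. Per the labels, the second channel of every array held pooled RNA of conventionally bred mice of the same genotype. The protocol states a pool of 6 animals and the labels list 4 mouse identifiers per pool, and which is right stayed open. RNA was extracted with RNeasy and labelled indirectly with Cy3 and Cy5, per the labels.

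The deposited table gave 1 log2 ratio per probe and array. Its normalization, scanner settings and filters are not given in the sources used here. The base of the logarithm was read from the values: a constant above 16 in size marked spots without a ratio on most arrays, near the log2 of a 16-bit scanner maximum. Values above 9 in size, 1183 in all on 883 probes, were treated as such constants and set to missing, and the largest remaining size was 8.34. They were positive on 748 spots with the cloned mouse in Cy5 and negative on 435 spots with it in Cy3. Array medians lay between -0.07 and 0.04 in liver and between -0.05 and 0.08 in spleen, so the arrays were used as deposited, with no further centring or scaling. They split by dye in wildtype mice, at 0.032 to 0.079 with the cloned mouse in Cy5 and -0.067 to -0.013 with it in Cy3. In Dll1 liver they lay at -0.008 to 0.031 in Cy5 and -0.06 to -0.021 in Cy3, and in Dll1 spleen the dyes overlapped. The number of missing values was 59 to 230 per liver array and 248 to 2859 per spleen array. Signal over background was not analysed here, and the number of arrays limits the precision.

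Both dye orientations were read as already turned to one direction, cloned mouse over pool, and this departed from the rule set before the data were examined. By that rule the agreement of a mouse's 2 arrays was to decide, and failing that the sign of the correlation between the mean ratios of both orientations. The same-mouse correlations were too weak to decide, with means of 0.0575 in Dll1 liver, 0.0103 in Dll1 spleen, 0.0110 in wildtype spleen and -0.0719 in wildtype liver. The orientation means correlated at -0.258, -0.298, -0.384 and -0.700 in these groups, which by the rule would have meant that the Cy3 arrays still had to be turned. A dye effect specific to probes would give such a correlation in turned values too and cancel in the mean of 2 arrays. It would be shared by the groups, and the mean half-differences between orientations correlated across probes at 0.379, 0.476 and 0.487 among Dll1 liver, Dll1 spleen and wildtype spleen. In wildtype liver they correlated with the other groups at 0.0232 to 0.210, so its strong pattern is not explained by a shared dye effect. The split of the wildtype array medians by dye could come from values not yet turned or from a dye effect, and does not decide.

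Reasons found after the data were seen favoured values already turned, without settling it. On that reading all constants mean an empty Cy3 channel, in every group, wildtype liver included (78 in Cy5 and 60 in Cy3), and on the other they would mean an empty pool and never an empty clone. Hba-a1 lay at -2.04 in Cy5 and -2.40 in Cy3 for mouse 2 of the Dll1 spleens, against -0.21 and -0.26 for mouse 4. Its values in both orientations correlated over the 4 mice at 0.967 and 0.877 in Dll1 and wildtype spleen and 0.534 in Dll1 liver, but at -0.221 in wildtype liver. Hba-a1 is 1 gene, called in wildtype liver on the reading as deposited and named by a shift chosen from the same values. It is therefore no independent support for that reading. Agreement of probes of 1 gene over the mice, with the shift between rows and names left free over 2001 shifts, stood out by 6.30 SDs as deposited and by 3.42 SDs at most with the Cy3 arrays turned. With each group centred it reached 3.59 and 3.46 SDs, and in the group means 3.37 to 3.89 and 3.27 to 3.54 SDs, which does not separate the readings. Which of clone and pool stands on top rests on the word order of the titles, and turning it would exchange all higher and lower values.

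Gene names needed a correction that was chosen after the data were examined, and after counts under the names as given had been seen. The reference table of this platform lists 12771 probes with a gene, all with 1 symbol and all matched to a current symbol through their gene number. Looked up by row number as given, probes of the same gene were no more alike than random probes: the mean Pearson correlation of 2171 such pairs over the mice was -0.000694. Each of 2001 shifts was then scored by this agreement alone, without regard to calls or gene lists. Reading each row's gene 11 places earlier gave 0.0562 over 2258 pairs, 6.30 SDs above the other shifts, whose highest was 0.0323. With each group centred, this shift still ranked 1, but at 0.0376 against 0.0362 for the next. Liver alone then ranked it 15 and spleen alone 2. By the group means it ranked 175, 12, 25 and 1 in Dll1 liver, Dll1 spleen, wildtype liver and wildtype spleen. The clear lead was thus seen only without centring. In a separate check, the coherence of the gene lists ranked the same shift first of 601 in liver and in spleen, where the names as given ranked 450 and 315. Stretches of the table were then scored over 121 shifts, with the partner probe of each pair held at the chosen shift. Of 7 stretches 5 picked the same shift, and the stretches from row 9001 to 12000 and from 12001 to 15000 did not. Since the partners stood at the chosen shift, this is not independent of the choice. The origin of the shift is unknown. With it, 12760 of 20794 rows had a name (9026 genes) and 8034 had none. Among genes named in the text, Dhx58, Spata17, Tsr1, Lypd4, Hoxa4, Tbl3, Snw1, Dek, Trappc4, Hspa5, Cth and at least 1 probe of Actb, Ptprc, Pcna, Car2, Lyz2, Sparc and H2az1 lay in the unresolved stretches. Every named result rests on this shift, and counts of features depend on it in part, since probes are averaged by name: with the names as given 18 passed in wildtype liver, 35 in the liver mean and 9 between organs in wildtype clones, against 14, 29 and 0. Probes of 1 gene were averaged per array over those present, and probes without a name stayed single. The 2 arrays of a mouse can therefore rest on different probes of a gene. In the text, a feature is such a gene or unnamed probe.

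Ratios were averaged over both arrays of a mouse, and a feature was tested where at least 3 of 4 mice of each group compared had both. limma 3.58.1 in R 4.3.3 was used (lmFit, contrasts.fit and eBayes), with two-sided tests and Benjamini-Hochberg adjustment at 0.05. Each group mean was tested against 0 in a fit of both cohorts of an organ, as were the mean of both cohorts and their difference, and the difference between organs within a cohort was tested in a fit of all 4 groups. The pool counts as 1 control sample, so a test against 0 leaves out the spread between control animals. The p-values describe the spread between cloned mice. The labels place liver and spleen of the same mice in both organs. Same-mouse deviations correlated at 0.000921 to 0.0935 across the organs, so a fit with the mouse as a block was run as an alternative.

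Gene lists numbered 38 and covered Notch signalling, imprinting, metabolism, stress, cell division, immunity and the cell types of liver, spleen and neighbouring tissue. They were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry. The mean correlation between members was 0.546 for hepatocyte genes in liver, and 0.256 and 0.225 for erythroid and ribosomal protein genes in spleen. For some other lists it lay near or under 0, as for marginal zone B cells in spleen at -0.125. Where it is high, p-values at the preset correlation come out too small. The groups, tests, lists, naming rule and first set of alternatives were set before the data were examined. The rule named, per cohort and organ, up to 10 genes in each direction with the largest change that passed with the same sign on all 8 arrays, filled up to 5 with the smallest p among those that did not pass. For differences and means over cohorts it named up to 5 per direction that passed, or otherwise the 3 with the smallest p. For each list described it named up to 4 members with the smallest p, and always Dll1 and the members of the Notch list at an unadjusted p under 0.05.

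Alternatives chosen at that time were centring, scaling, single probes, other rules for missing values, single dye orientations, a fit of single arrays with the mouse as a random block and a dye term, other sets of groups in the fit, robust eBayes, the mouse as a replicate block, and leaving out each mouse. Alternatives added after the data were seen were the names as given, names left out in the unresolved stretches, constants kept as values, and Cy3 arrays turned, the last for counts only.

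The fits were tested on simulated data with 50 features changed by each of 4 sizes, once per comparison. Spread was set either to 1 SD per feature times each group's median spread, or to each feature's own SD in each group, and values are given in this order. A log2 change of 0.5 was recovered for 88% and 90% of features in Dll1 liver, 96% and 96% in wildtype liver, 66% and 66% for the difference of the cohorts in liver, and 2% and 4% in either spleen cohort. A change of 2 was recovered for 92% and 94% of features in Dll1 spleen and 82% and 84% in wildtype spleen. False calls were 29 of 183 and 71 of 231 in Dll1 liver, 4 of 171 and 18 of 193 in wildtype liver, 7 of 188 and 20 of 201 for the liver mean, 23 of 85 and 67 of 139 in Dll1 spleen, 127 of 223 and 274 of 374 between organs in Dll1 clones, and 4 of 83 and 36 of 122 between organs in wildtype clones. They were 5 of 147 and 13 of 158 for the difference in liver, 0 of 63 and 6 of 75 in wildtype spleen, 1 of 39 and 4 of 50 for the difference in spleen, and 8 of 103 and 16 of 107 for the spleen mean, so the share of false calls can exceed 5%. In 20 simulations without any change and with the first kind of spread, wildtype liver and the liver mean gave 0 calls, and the difference between organs in Dll1 clones gave 48.95 calls on average. Simulated features were drawn independently of each other and without an error of the pool. Real genes vary together, so counts above the simulated ones do not by themselves show changes.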

Results

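Liver and spleen of mice cloned by nuclear transfer were compared with pooled RNA of conventionally bred mice of the same genotype. Dll1 encodes a ligand of Notch receptors, and the label of the mutant pool gives its animals as heterozygotes. There were 4 cloned mice per genotype, each with 2 dye-swapped arrays per organ, which made 32 arrays. All values are log2 ratios, likely of clone over pool, and turning the direction would exchange higher and lower. The dye-swapped arrays were read as already turned to this direction, against the rule set beforehand and for reasons seen in the data. Over all groups this reading was favoured but not settled. In wildtype liver the constants favoured it, but other checks did not. There the orientation means correlated at -0.700 and the Hba-a1 values of both orientations at -0.221. Arrays of the same mouse correlated at -0.0719, against 0.0241 between mice. Under the other reading 9262 features passed in wildtype liver and no list had a call in liver. Lists then had 1 call in wildtype spleen, 1 between organs of Dll1 clones and 0 in the remaining comparisons. Gene names were read with a shift of 11 rows between values and names, which was found from the data after they were examined. The median SD between mice was 0.109 in Dll1 liver and 0.0866 in wildtype liver, against 0.399 and 0.257 in the spleens, so that smaller differences could be resolved in liver.

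Dll1 itself was given first because the cohorts are defined by it, although clone and pool share the genotype and the ratio does not check it. In Dll1 liver it lay at -0.07 ± 0.29 (SD, n = 4 mice) and in wildtype liver at -0.40 ± 0.42 (SD, n = 4 mice). In spleen it lay at 0.15 ± 0.67 in Dll1 mice and 0.25 ± 0.75 in wildtype mice (SD, n = 4 mice each). None passed by limma, with adjusted p = 0.466 in wildtype liver and higher in the other groups, and the difference of the cohorts did not pass in liver (0.33 ± 0.20, SE, adjusted p = 0.934) or spleen (-0.10 ± 0.44, SE, adjusted p = 0.975). Dll1 mouse 4 stood apart in liver at -0.51, and without it the mean of the Dll1 livers turned to 0.07. The 2 probes of Dll1 differed, at -0.76 and -0.04 in wildtype liver and -0.14 and -0.006 in Dll1 liver. They lay at 0.04 and 0.46 in wildtype spleen, and had opposite signs in Dll1 spleen (-0.495 and 0.24). Where a probe was missing on some arrays, the gene value can lie outside both, as in the spleen difference (-0.53 and -0.22).

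The first question was how the liver of wildtype clones differed from that of conventional wildtype mice. Hba-a1, a haemoglobin alpha chain, fell by 0.56 (SE 0.07, adjusted p = 0.0287), lower in 4 of 4 mice and with all 6 probes of the same sign. Fbxo41, which encodes an F-box protein, fell by 0.58 (SE 0.07, adjusted p = 0.0210), and Actb, cytoplasmic beta-actin, fell by 0.28 (SE 0.04, adjusted p = 0.0434), each in 4 of 4 mice. Fga, the fibrinogen alpha chain, fell by 0.49 (SE 0.06, adjusted p = 0.0295), and Nup155, a nuclear pore protein, fell by 0.52 (adjusted p = 0.0325). Nup155 lay outside the naming rule here and was added after the result was seen. H3f3a, which encodes histone H3.3, lay at -0.75 (adjusted p = 0.0879) and Mark3, a kinase, at -0.36 (adjusted p = 0.0879), and neither passed.

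In all, 14 of 16948 features passed in wildtype liver by limma, 0 higher and 14 lower, of which 5 had a gene name and 9 had none. At an unadjusted p under 0.05 there were 1516, 784 higher and 732 lower, where simulations with no change gave 539 on average. Here and below the simulated features were independent of each other and of any pool error, so such an excess does not by itself show changes. Rises with the smallest p did not pass: Cilk1 lay at 0.22, Lypd4 at 0.25, Hoxa4 at 0.16, Tbl3 at 0.21 and Tssk6 at 0.18, with adjusted p-values from 0.326 to 0.373. The count was 0 after scaling the arrays to one spread, and 0 without mouse 1, mouse 3 or mouse 4 in turn. It was 7 without mouse 2.

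Genes of hepatocytes were lower as a group in wildtype liver: 20 of 20 members lay under 0, with a median of -0.19 (camera adjusted p = 5.38e-16). The call was lost at adjusted p = 0.251 with an estimated correlation, 0 members passed over all features, and 13 fell when adjusted over the list alone. Members with the smallest p were Fgb, the fibrinogen beta chain, at -0.35 (SE 0.06), Trf, transferrin, at -0.19 (SE 0.04, its 2 probes of opposite sign), Ttr, transthyretin, at -0.23 (SE 0.05) and Tat, tyrosine aminotransferase, at -0.31 (SE 0.07). Of the acute phase list, 20 of 22 members lay under 0 (camera adjusted p = 3.18e-09, against adjusted p = 0.154 with an estimated correlation). Of these, 1 fell over all features and 6 when adjusted over the list alone, and Fgl1, a fibrinogen-like protein secreted by liver, lay at -0.30 (SE 0.05) and the interleukin-6 receptor gene Il6ra at -0.40 (SE 0.08).

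Lists of transcripts used in every tissue also lay lower in wildtype liver. Ribosomal protein genes had a median of -0.06 (51 of 60 under 0, adjusted p = 1.62e-08, or adjusted p = 0.251 with an estimated correlation, 0 fell adjusted over the list alone), with Rpl39 at -0.23 and Rps28 at -0.27. Oxidative phosphorylation genes had a median of -0.05 (51 of 73 under 0, adjusted p = 0.000181, or adjusted p = 0.341 with an estimated correlation, 0 fell adjusted over the list alone), with Ndufs1 at -0.16. Smaller calls downward were made for endoplasmic reticulum stress (adjusted p = 0.00351), oxidative stress (0.00415), xenobiotic metabolism (0.00626), heat shock and chaperones (0.0121) and bile acid metabolism (0.0244). All 5 were lost, at adjusted p = 0.154, 0.341, 0.387, 0.251 and 0.251 with an estimated correlation. Adjusted over the list alone, 4, 1, 0, 0 and 0 of their members fell, and Hspa5, an endoplasmic reticulum chaperone, lay at -0.28 (SE 0.06).

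In the liver of Dll1 clones, Fgl1 lay at -0.45 (SE 0.05) and Fbxo41 at -0.53 (SE 0.07), both lower in 4 of 4 mice, and both missed the threshold at an adjusted p = 0.0902. Dhx58, an RNA sensor of the interferon system, lay at -0.28 (SE 0.04, adjusted p = 0.197), and Elmo2 and Glis3 lay at -0.28 and -0.19 (both adjusted p = 0.348). Rises with the smallest p were Ptpn5 at 0.20 with its 2 probes of opposite sign, Spata17 at 0.15, Car13, a carbonic anhydrase, at 0.17, Rd3 at 0.14 and Tsr1 at 0.16, with adjusted p-values from 0.368 to 0.470. No feature passed, 0 of 16916 by limma, and 1584 had an unadjusted p under 0.05, where simulations with no change gave 1247 on average.

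Hepatocyte genes lay lower in Dll1 liver too, 18 of 20 under 0 with a median of -0.09 (camera adjusted p = 1.89e-06). The list mean was -0.002, -0.214, -0.032 and -0.159 in mice 1, 2, 3 and 4, so mice 2 and 4 carried most of it. The call was lost at adjusted p = 0.813 with an estimated correlation, and 3 members fell when adjusted over the list alone. Arg1, arginase of the urea cycle, lay at -0.23 (SE 0.05) and Tat at -0.28 (SE 0.07). Acute phase genes had a median of -0.12 (18 of 22 under 0, camera adjusted p = 1.89e-06, or adjusted p = 0.436 with an estimated correlation), and 7 fell adjusted over the list alone. Orm1 lay at -0.47 (SE 0.11) and Saa1, serum amyloid A, at -0.36 (SE 0.09). Ribosomal proteins (adjusted p = 1.89e-06), oxidative phosphorylation (0.0262) and xenobiotic metabolism (0.0475) also had calls downward. Those calls were lost at adjusted p = 0.679, 0.813 and 0.911 with an estimated correlation, and 0 of their members fell adjusted over the list alone.

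The mean of both cohorts asked which features were shifted on average over both genotypes in liver, where the pools came from different animals. A shift in 1 cohort alone can move this mean, so it does not test sharing, and no feature passed in Dll1 liver alone. Fgl1 fell by 0.38 (SE 0.04, adjusted p = 0.00328), Fga by 0.37 (SE 0.05, adjusted p = 0.0119) and Fgb by 0.31 (SE 0.04, adjusted p = 0.0188), each lower in 8 of 8 mice. Fbxo41 fell by 0.56 (SE 0.05, adjusted p = 0.00285), Hba-a1 fell by 0.44 (SE 0.05, adjusted p = 0.00856) and Nup155 fell by 0.41 (SE 0.05, adjusted p = 0.00980), each in 8 of 8 mice. H3f3a fell by 0.60 (SE 0.09, adjusted p = 0.0360) in 8 of 8 mice. Sumo3, a ubiquitin-like modifier, fell by 0.42 (SE 0.06, adjusted p = 0.0470) in 7 of 7 mice, but lay at 0.66 with constants kept as values. In all, 29 of 16901 features passed by limma, 0 higher and 29 lower, 16 of them with a gene name. At an unadjusted p under 0.05 there were 2219, 959 higher and 1260 lower, where simulations with no change gave 881 on average. Single arrays with the mouse as a random block and a dye term gave 218, 29 higher and 189 lower.

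Of the hepatocyte list, 20 of 20 members lay under 0 in this mean (median -0.14, camera adjusted p = 1.75e-14, or adjusted p = 0.251 with an estimated correlation). Of these, 1 fell over all features and 15 when adjusted over the list alone. Of the acute phase list, 17 of 22 lay under 0 (median -0.11, camera adjusted p = 1.90e-10, or adjusted p = 0.155 with an estimated correlation), 3 fell over all features and 12 when adjusted over the list alone. Orm1 lay at -0.45, Arg1 at -0.20 and Tat at -0.29, with adjusted p-values of 0.0567, 0.0567 and 0.0774. Ribosomal protein genes had a median of -0.05 with 53 of 60 under 0 (adjusted p = 4.68e-11, or adjusted p = 0.251 with an estimated correlation) and 4 fell adjusted over the list alone, Rpl23 lying at -0.26. Oxidative phosphorylation had a median of -0.04 (adjusted p = 8.88e-05, or adjusted p = 0.322 with an estimated correlation), xenobiotic metabolism -0.05 (adjusted p = 0.00118, or adjusted p = 0.407 with an estimated correlation) and bile acid metabolism -0.09 (adjusted p = 0.0114, or adjusted p = 0.251 with an estimated correlation), and 0 members of these fell adjusted over the list alone. The count of 29 became 6 after scaling and 0 with the spleens in the fit, and leaving out single mice gave 11 to 49.

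Whether the shift differed between genotypes was asked by the difference of the cohorts in liver. Renbp, a renin-binding protein gene, differed by 0.34 (SE 0.06), Slc25a3, the mitochondrial phosphate carrier, by 0.71 (SE 0.15) and Fgf2, a fibroblast growth factor, by 0.32 (SE 0.07), Dll1 minus wildtype, and none passed (adjusted p = 0.934 each). By limma 0 of 16901 features passed, and 828 had an unadjusted p under 0.05, against 875 on average in simulations with no change. No list had a call by camera. Across 16901 features the mean ratios of the cohorts correlated at Pearson r = 0.279 and Spearman rho = 0.276, and 59.2% had the same sign. Features are not independent replicates.

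**Figure D1:**
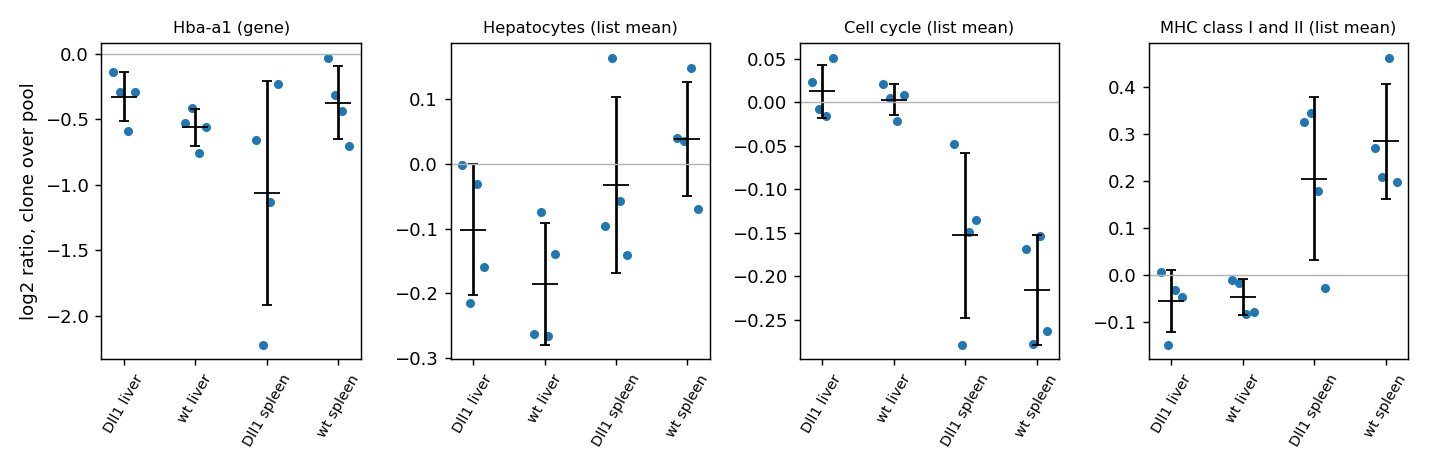
Log2 ratio of clone over pool for Hba-a1 and for the mean of 3 gene lists in each mouse (dots), by cohort and organ, with the group mean (horizontal bar) and SD (error bar, n = 4 mice). Hba-a1 lay under 0 in every group (means -0.33, -0.56, -1.06 and -0.37 from left to right), and each panel has its own axis.

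In the spleen of wildtype clones, genes of cell division lay lower. Of the cell cycle list, 33 of 41 members lay under 0 with a median of -0.18 (camera adjusted p = 2.70e-10), and the call was lost at adjusted p = 0.0632 with an estimated correlation. None passed over all features and 8 fell when adjusted over the list alone, with Cdc6, a replication licensing factor, at -0.66 (SE 0.13), Rrm2, a ribonucleotide reductase subunit, at -0.70 (SE 0.15), Pcna, the replication clamp, at -0.74 (SE 0.18) and Top2a, a topoisomerase, at -0.52 (SE 0.14). Erythroid genes had a median of -0.28 (17 of 22 under 0, camera adjusted p = 3.30e-08, or adjusted p = 0.434 with an estimated correlation), and 5 fell adjusted over the list alone. Car2, a carbonic anhydrase, lay at -1.03 (SE 0.25), Prdx2, a peroxiredoxin abundant in red cells, at -0.95 (SE 0.26) and Hba-a1 at -0.37 ± 0.28 (SD, n = 4 mice).

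Antigen presentation and B cell genes lay higher in the same spleens. Of the MHC list, 10 of 11 members lay above 0 with a median of 0.21 (camera adjusted p = 1.02e-06, or adjusted p = 0.256 with an estimated correlation), and 4 rose adjusted over the list alone. Cd74, the invariant chain, lay at 0.52 (SE 0.12) and B2m, beta-2-microglobulin, at 0.45 (SE 0.14). B cell genes had a median of 0.13 (15 of 18 above 0, adjusted p = 0.0162, or adjusted p = 0.256 with an estimated correlation, 1 rose adjusted over the list alone), with Ms4a1, the B cell antigen CD20, at 0.71 (SE 0.11), while Cd24a lay at -0.74 (SE 0.26), lower in 4 of 4 mice. Marginal zone B cell genes had a median of 0.08 (7 of 8 above 0, adjusted p = 0.0244, or adjusted p = 0.256 with an estimated correlation, 1 rose adjusted over the list alone), with Plac8 at 0.53 and Notch2, the receptor needed for these cells, at 0.31. Ribosomal proteins had a call upward (adjusted p = 0.0244, or adjusted p = 0.667 with an estimated correlation) and oxidative stress downward (adjusted p = 0.0162, or adjusted p = 0.434 with an estimated correlation), and 0 of their members passed adjusted over the list alone.

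Single genes with the smallest p in wildtype spleen were Lyz2, a lysozyme of myeloid cells, at 0.76 (SE 0.11), Coch at 0.70 (SE 0.11), Ifi30, a lysosomal thiol reductase, at 0.58 (SE 0.11), Cd28, a T cell costimulator, at 0.60 (SE 0.12), Dek, a chromatin protein, at -0.84 (SE 0.15), Prps1 at -0.75 (SE 0.17) and Trappc4 at -0.72 (SE 0.16). Adjusted p-values ran from 0.761 to 0.975. Of 16470 features 0 passed by limma, and 617 had an unadjusted p under 0.05, against 328 on average in simulations with no change. The simulated fit recovered 42% of changes of 1 in these spleens.

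In the spleen of Dll1 clones, H2-Eb1, an MHC class II chain, lay at 1.34 (SE 0.19) and Ptprc, the leukocyte antigen CD45, at 0.73 (SE 0.12), both higher in 4 of 4 mice. Rpl32 lay at 0.47, Ifi30 at 0.45 and Mt3 at 0.49. Of the 3 probes of Mt3, the only 1 measured on both arrays of a mouse lay at 0.23. The neutrophil genes S100a9 and Ngp lay at -0.82 (SE 0.15) and -0.62 (SE 0.12), lower in 4 of 4 mice, beside Sh3bp5l at -0.66, Commd1 at -1.47 and Prap1 at -0.94. None of these passed (adjusted p = 0.389 each). No feature passed, 0 of 15879 by limma, and 1638 had an unadjusted p under 0.05, where simulations with no change gave 1547 on average.

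Erythroid genes had a median of -0.35 in Dll1 spleen (19 of 22 under 0, camera adjusted p = 1.18e-06, or adjusted p = 0.611 with an estimated correlation), and 2 fell adjusted over the list alone. Hba-a1 lay at -1.06 ± 0.86 (SD, n = 4 mice), Rhd, a blood group protein, at -0.83 (SE 0.22) and Alas2, which starts haem synthesis in red cells, at -0.56 (SE 0.18). Cell cycle genes had a median of -0.15 (30 of 40 under 0, adjusted p = 0.00574, or adjusted p = 0.611 with an estimated correlation, 0 fell adjusted over the list alone), with Top2a at -0.61 (SE 0.13), while H2az1, a histone variant, lay at 0.36 (SE 0.12), higher in 4 of 4 mice, its 2 probes of opposite sign. Neutrophil genes had a median of -0.16 (8 of 15 under 0, adjusted p = 0.0335, or adjusted p = 0.611 with an estimated correlation), and 3 fell adjusted over the list alone. Ribosomal proteins had a median of 0.13 (50 of 60 above 0, adjusted p = 0.00244, or adjusted p = 0.948 with an estimated correlation, 0 rose adjusted over the list alone).

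In the mean of both cohorts in spleen, Ms4a1 lay at 0.57 (SE 0.08), Coch at 0.54 (SE 0.08) and Ifi30 at 0.51 (SE 0.07), higher in 8 of 8 mice, and did not pass (adjusted p = 0.265 each). The cell cycle list had 33 of 40 members under 0 (median -0.20, camera adjusted p = 1.93e-08, or adjusted p = 0.113 with an estimated correlation), and 5 fell adjusted over the list alone, with Top2a at -0.57 and Mcm2 at -0.61. The erythroid list had 17 of 22 under 0 (median -0.33, adjusted p = 1.81e-10, or adjusted p = 0.327 with an estimated correlation), and 11 fell adjusted over the list alone, with Car2 at -0.89 and Prdx2 at -0.89. The MHC list had 10 of 11 above 0 (median 0.27, adjusted p = 5.49e-05, or adjusted p = 0.327 with an estimated correlation), and 5 rose adjusted over the list alone, with H2-Eb1 at 0.89 and Cd74 at 0.45. Marginal zone B cells (adjusted p = 0.0319), stroma (0.0470) and ribosomal proteins (0.000143) had calls upward, lost at adjusted p = 0.327, 0.327 and 0.582 with an estimated correlation. Of their members 2, 0 and 0 rose adjusted over the list alone, and Sparc, a matrix protein, lay at 0.25 and Col4a2, a basement membrane collagen chain, at 0.50. By limma 0 of 15635 features passed, and 1285 had an unadjusted p under 0.05, against 896 on average in simulations with no change.

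In spleen the mean ratios of the cohorts correlated at Pearson r = 0.0837 and Spearman rho = 0.0883 across 15635 features, with the same sign for 53.2%. In single dye orientations, Cy5 and Cy3, r was 0.417 and 0.343 in spleen and 0.0745 and 0.102 in liver, so the organs are not ranked by it. In the difference of the cohorts, Nars, an aminoacyl-tRNA synthetase gene, lay at 1.27 (SE 0.21), Fabp5, a fatty acid binding protein, at 1.01 (SE 0.20) and Fam120b at 1.30 (SE 0.28), and none passed (adjusted p = 0.868 each). No feature passed, 0 of 15635 by limma, and 742 had an unadjusted p under 0.05, against 891 on average in simulations with no change. Neutrophil genes differed as a list with a median of -0.31 (9 of 15 under 0, camera adjusted p = 0.0497, or adjusted p = 0.888 with an estimated correlation), 2 fell adjusted over the list alone, and the call ended when arrays were centred.

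The last question was whether the shift differed between liver and spleen. In Dll1 clones, 14 of 15863 features passed, 5 higher and 9 lower in liver than in spleen, among them Ktn1 at 0.84 (SE 0.14), Ngp at 0.63 (SE 0.11), Pja2 at -1.41 (SE 0.22), Kctd10 at -1.29 (SE 0.20), H2-Eb1 at -1.23 (SE 0.20), Rims3 at -1.14 (SE 0.13) and Mmp2, a matrix protease, at -0.83 (SE 0.13), with adjusted p-values from 0.0181 to 0.0407. Simulations with no change gave 48.95 such calls on average in this fit of all 4 groups, and 0.2 with the organs of Dll1 clones alone, so the 14 calls are not counted as changes. With the groups compared alone, or with the mouse as a replicate block, 0 features passed. In wildtype clones, Lyz2 lay at -0.77 (SE 0.11), Cd28 at -0.74 (SE 0.11) and Coch at -0.74 (SE 0.11), and none passed (adjusted p = 0.0512 each). Of 16451 features 0 passed by limma, and 1022 had an unadjusted p under 0.05, against 481 on average in simulations with no change. With the groups compared alone 16 passed, 8 higher and 8 lower in liver, where simulations with no change gave 0.15 on average and 2 at most. With the mouse as a replicate block 0 passed.

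Cell cycle genes differed between the organs of wildtype clones, with 33 of 41 members higher in liver relative to spleen and a median of 0.21 (camera adjusted p = 2.75e-10). The adjusted p was 0.00558 with an estimated correlation, and 9 members rose adjusted over the list alone. The list mean lay at -0.022 to 0.021 in the wildtype livers and at -0.278 to -0.154 in the wildtype spleens. The difference thus restates the lower values in spleen, whose own call was lost with an estimated correlation. Simulations of the organ comparison in wildtype clones with changes present gave 36 false calls of 122 with each feature's own spread, and 4 of 83 with scaled spread. With the Cy3 arrays turned 0 lists had a call in this comparison. Calls for MHC (median -0.19, adjusted p = 1.50e-07), hepatocytes (-0.24, adjusted p = 0.000431), erythroid cells (0.24, adjusted p = 2.11e-06) and ribosomal proteins (-0.13, adjusted p = 6.00e-07) were lost at adjusted p = 0.0863, 0.0898, 0.205 and 0.205 with an estimated correlation. Adjusted over the list alone, 5 and 1 members of the first 2 fell, 5 erythroid genes rose and 0 ribosomal protein genes fell. Calls for endoplasmic reticulum stress (adjusted p = 0.00593), glucose metabolism (0.0379), B cells (0.0429) and marginal zone B cells (0.0466), all lower in liver, were lost at adjusted p = 0.0898, 0.102, 0.102 and 0.125 with an estimated correlation. Adjusted over the list alone, 1, 0, 2 and 2 of their members fell.

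In Dll1 clones, cell cycle (median 0.18, adjusted p = 0.00521), neutrophil (0.14, adjusted p = 0.0369) and erythroid genes (0.37, adjusted p = 7.13e-07) had calls upward, and MHC (-0.20, adjusted p = 0.0103) and ribosomal proteins (-0.18, adjusted p = 7.07e-07) downward. All 5 were lost at adjusted p = 0.393 with an estimated correlation. Adjusted over the list alone, 1 cell cycle gene passed upward and 1 downward, 3 neutrophil and 7 erythroid genes upward, and 4 MHC and 4 ribosomal protein genes downward. These members come from the fit of all 4 groups whose 14 calls are not counted as changes, and are not counted either.

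The test fry asks whether the genes of a list move one way on balance and does not compare them with other genes. It called 1 list in Dll1 liver, 2 in wildtype liver, 7 in the liver mean, 2 in Dll1 spleen, 3 in wildtype spleen, 6 in the spleen mean, 7 and 9 between organs of Dll1 and wildtype clones, and 0 for both differences of the cohorts. Of the lists called by camera at the preset correlation, fry called 1 of 5, 2 of 9, 4 of 6, 0 of 4, 3 of 7, 4 of 6, 4 of 5 and 7 of 9 in the same order, and 0 of 1 for the spleen difference. The acute phase list had fry adjusted p = 0.0410 in Dll1 liver, 0.0264 in wildtype liver and 0.00471 in the liver mean, and the hepatocyte list 0.304, 0.0728 and 0.0328. The cell cycle list had fry adjusted p = 0.0924 in Dll1 spleen, 0.0243 in wildtype spleen and 0.00588 in the spleen mean, and the erythroid list 0.122, 0.241 and 0.0540. Macrophage genes had a fry call upward in the spleen mean (adjusted p = 0.00588), where camera gave adjusted p = 0.166. For changes in either direction fry called 12 lists in Dll1 liver, 9 in wildtype liver, 24 in the liver mean, 9 in Dll1 spleen, 6 in wildtype spleen, 15 in the spleen mean, 10 and 8 between organs, and 0 and 1 for the differences in liver and spleen.

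Notch pathway genes as a list had no call by camera in any comparison, with 36 members at a median of -0.03 in the liver mean (camera adjusted p = 0.120, 1 fell adjusted over the list alone) and 33 members at 0.03 in the spleen mean (camera adjusted p = 0.375). For changes in either direction fry called it in Dll1 liver, wildtype liver and the liver mean (adjusted p = 0.0353, 0.0283 and 0.00461), and for 1 direction in no comparison. Such calls in either direction were made for 12, 9 and 24 of 38 lists there, so they are not particular to the Notch list. Of its members at an unadjusted p under 0.05 in the liver mean, Dll1 lay at -0.24 (SE 0.10, adjusted p = 0.360), Hes7 at -0.22 (SE 0.05), Hes5 at -0.26 (SE 0.07), Hey1 at -0.16 (SE 0.05), Ncstn, a subunit of gamma-secretase, at -0.12 (SE 0.04), Aph1a at -0.07, Hes6 at -0.06 and Notch4 at 0.10, and none passed (adjusted p from 0.143 to 0.378). The 2 probes of Dll1 lay at -0.45 and -0.02 in the liver mean. Members at an unadjusted p under 0.05 in single cohorts did not pass either. In wildtype liver these were Hes5 at -0.30, Hes7 at -0.27, Hey1 at -0.16, Hey2 at -0.22, Notch4 at 0.11, Snw1 at 0.10 and Dll1 as given above. In Dll1 liver they were Aph1a at -0.12, Hes7 at -0.17, Hey1 at -0.16, Ncstn at -0.16 and Dll3 at 1.04 over 3 mice, and in the difference of the cohorts Hey2 at 0.39 and Pofut1 at -0.16.

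In Dll1 spleen Adam17, a protease that cuts Notch receptors, lay at 0.40 and Rfng, which adds sugars to them, at -0.35, and in wildtype spleen Notch2 lay at 0.31. Their values in the spleen mean were 0.29, -0.26 and 0.27. Between organs of Dll1 clones, Adam10 lay at -0.28, Adam17 at -0.43, Hes5 at -0.42, Hes7 at -0.47, Ncstn at -0.41 and Rfng at 0.38, and between organs of wildtype clones Hes5 at -0.44, Hes6 at -0.22 and Notch2 at -0.43. Dll1 itself differed between organs at -0.22 (SE 0.37) in Dll1 clones and -0.65 (SE 0.37) in wildtype clones. None of these passed. Imprinted genes, of interest because cloning can disturb imprinting, had medians of 0.01 over 30 genes in the liver mean (camera adjusted p = 0.798) and 0.00 over 28 in the spleen mean (camera adjusted p = 0.708), with 0 passing adjusted over the list alone.

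**Figure D2:**
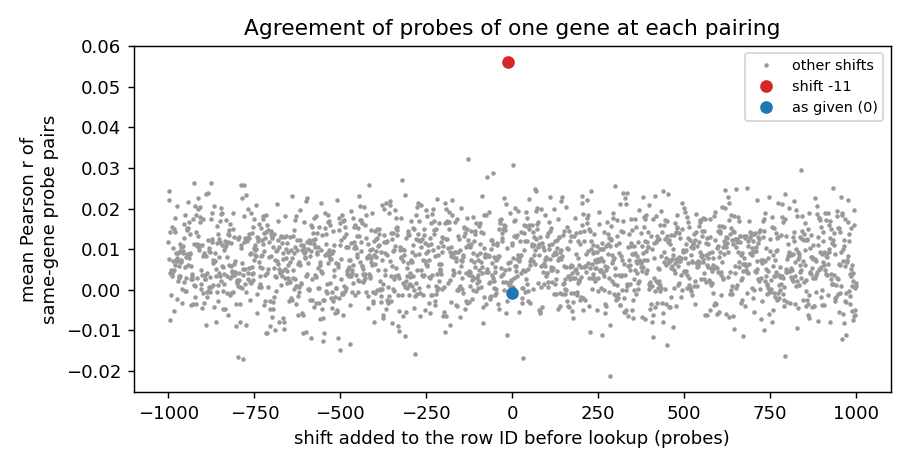
Mean Pearson correlation of probes of one gene over the mice (vertical axis) for each shift between value rows and gene names in probes (horizontal axis). The shift used, -11, reached 0.0562, the names as given -0.000694, and the highest of the other shifts 0.0323. Groups were not centred here, and with centring the lead was 0.0376 against 0.0362.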

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

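The tests of blood left in the organs, of 1 unusual pool, of abundant transcripts in general and of the unequal spread between groups were chosen after the result was seen.

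Of 115 groups of 4 mice tested for 1 mouse far from the others, 5 stood out, where 5.75 would by chance. They were Spata17 in Dll1 liver mouse 2 at 0.21, against 0.12 to 0.14 in the others, Dll1 in Dll1 liver mouse 4 at -0.51, against 0.02 to 0.10, and Cilk1 in wildtype liver mouse 1 at 0.32, against 0.18 to 0.19. The others were H2-Eb1 in Dll1 spleen mouse 4 at 0.81, against 1.47 to 1.58, and Rpl32 in Dll1 spleen mouse 1 at 0.31, against 0.51 to 0.53.

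Genes that differed between liver and spleen of Dll1 clones by the test of the difference were Ktn1 (0.84), Ngp (0.63), Pja2 (-1.41), Kctd10 (-1.29), H2-Eb1 (-1.23), Rims3 (-1.14) and Mmp2 (-0.83). The fit pooled the spread of all 4 groups, and simulated features without change gave 48.95 calls on average and 80 at most, against 14 observed, and 0.2 with the organs of Dll1 clones fitted alone. Unequal spread in the pooled fit may therefore account for the count. The 8 splits that part every mouse's organs are too few for a share under 0.05, with 14 in the real one, the 1 split to reach it, and 0 in the highest other.

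Hba-a1 lay lower in all 4 groups and the erythroid list in the spleens, while the erythroid list means of the livers lay between -0.08 and 0.04. In spleen the list mean was -0.40 (SD 0.37) in Dll1 and -0.29 (SD 0.15) in wildtype clones, under 0 by more than the SD in 2 of 2 cohorts with pools of different animals. Without mouse 2 or mouse 3 the Dll1 mean was -0.25 (SD 0.28) or -0.34 (SD 0.44), no longer beyond the SD, so 1 unusual pool stays open. With an estimated correlation the erythroid list had no call in the spleen mean (adjusted p = 0.327). Blood left in the organs of the pooled animals would lower neutrophil and platelet genes too: over the 8 spleens the neutrophil list mean was -0.121 (SE 0.0569) and the platelet list mean 0.0303 (SE 0.0595), which decides neither way. Fewer dividing erythroid cells are a candidate explanation, tested by the list means of both kinds over the 8 spleens, Pearson r = 0.627 (permutation p = 0.0912) and Spearman rho = 0.714 (permutation p = 0.0568), the only relation computed. Without the 2 farthest spleens r was 0.761, and within cohorts 0.802, so this stays open, as does a difference in how the animals were bled.

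Hepatocyte and acute phase genes lay lower in the liver of clones by camera at the preset correlation, and the calls were lost in the liver mean with an estimated correlation (adjusted p = 0.251 and 0.155). The hepatocyte list mean lay under 0 in 4 of 4 sets by cohort and dye (-0.12 and -0.09 in Dll1, -0.21 and -0.14 in wildtype for Cy5 and Cy3), but this rests on the reading of the Cy3 arrays as already turned. With them turned the 2 orientations would have opposite signs in both cohorts, so dye bias left in the means stays open. A loss of signal of abundant transcripts in general would lower ribosomal and oxidative phosphorylation genes too, and their medians lay at -0.0535 and -0.0409, so a technical loss of that kind may contribute. A shift with the cloning itself stays open, untested.

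For the counts themselves, 8 of 35 splits of the livers gave as many features at an unadjusted p under 0.05 as the real 828 between cohorts, and the highest other gave 1349, so chance was not excluded. For the spleens 2 of 35 did, with 742 real and 796 at most in the others, and chance was not excluded. Between organs in wildtype clones the 8 splits that part every mouse's organs are too few for such a share, with 1022 real and 486 in the highest other, and simulations with no change gave 481 on average. For the liver mean, 1 of 100 turns of the mice's signs, the real one, gave 29 features, and the highest other gave 4. Chance in the signs of the mice was thus unlikely, at the smallest share that 100 turns can give. Turning signs covers neither the error of each pool, shared by all 4 mice of a cohort, nor a dye effect left in the mean of every mouse. For wildtype liver 8 turns are too few for such a share, with 14 real and 0 in the highest other.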

How the results depend on the processing

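Alternatives on names as given, on names in unresolved stretches, on kept constants and on turned Cy3 arrays were chosen after the data were seen. The cause was not tested unless stated.
Among the main results, 153 alternative values stayed within the set limits and 111 moved, and among single genes 1009 kept their side of the threshold, 95 lost it, 58 gained it and 11 turned.
With the Cy3 arrays turned, 856 features passed in Dll1 liver, 9262 in wildtype liver, 7022 for the liver difference, 7173 for the liver mean, 730 in Dll1 spleen, 188 in wildtype spleen, 2095 for the spleen mean, 0 for the spleen difference, and 699 and 2340 between organs in Dll1 and wildtype clones. List calls then numbered 1 in wildtype spleen, 1 between organs in Dll1 clones and 0 elsewhere, under names chosen from the deposited values.
Cy5 alone and Cy3 alone gave 117 and 43 features in Dll1 liver, 5600 and 7295 in wildtype liver, 3076 and 3871 for the liver difference, 3378 and 5285 for the liver mean, 829 and 160 for the spleen mean and 991 and 476 between organs in wildtype clones. Cy5 alone gave 6 in Dll1 spleen, 1 in wildtype spleen and 258 between organs in Dll1 clones, where Cy3 alone gave 0, 0 and 13. Either orientation gave 0 for the spleen difference. The correlation of the cohorts became 0.0745 and 0.102 in liver and 0.417 and 0.343 in spleen.
Single arrays with the mouse as a random block and a dye term gave 12 in Dll1 liver, 54 in wildtype liver, 218 for the liver mean (29 higher and 189 lower), 1 and 8 in Dll1 and wildtype spleen, 65 for the spleen mean, and 54 and 37 between organs in Dll1 and wildtype clones.
Scaling gave 0 in wildtype liver, 6 for the liver mean and 1 between organs in Dll1 clones. Centring gave 19 for the liver mean and 2 between organs in wildtype clones. Every probe as a feature gave 46 for the liver mean and 8 between organs in wildtype clones. A mouse with either array gave 19 for the liver mean and 7 between organs in Dll1 clones. Complete features gave 7 and 11 between organs in Dll1 and wildtype clones.
Only the groups compared gave 25 in wildtype liver and 0 and 16 between organs in Dll1 and wildtype clones. All 4 groups in one fit gave 0 for the liver mean, 87 for the spleen difference and 714 for the spleen mean. For the last 2, simulations with no change gave 254.5 and 253.9 on average and 330 and 328 at most. The 87 lay under these counts and the 714 above them. Unequal spread enters both, and the simulated features were independent of each other, so the 714 are not counted as changes. The mouse as a replicate block gave 0 between organs in Dll1 clones and 0 in wildtype clones. Title numbers across cohorts mark no shared animal, and as a replicate block they gave 0 for both differences of the cohorts.
Constants kept gave 6 in wildtype liver, 19 for the liver mean and 5 between organs in wildtype clones, where the names as given gave 9 and names left out in unresolved stretches 4.
With an estimated correlation 0 lists were called in every comparison except 1 between organs in wildtype clones, and with the names as given 0 lists were called in any comparison. Centring ended the 1 list called between the cohorts in spleen, giving 0.
Without 1 mouse each, counts ran from 0 to 1 in Dll1 liver, 0 to 7 in wildtype liver, 11 to 49 for the liver mean, 0 to 1 in Dll1 spleen and for the spleen mean, 2 to 63 between organs in Dll1 clones and 0 in the others. The correlation of the cohorts ran from 0.189 to 0.312 in liver and 0.0609 to 0.107 in spleen. The liver mean gave 16, 49 and 18 without Dll1 mouse 2, 3 and 4, and 11, 19, 14 and 17 without wildtype mouse 1, 2, 3 and 4. The organ difference in Dll1 clones gave 63, 3 and 2 without mouse 1, 2 and 3. The single calls came without Dll1 liver mouse 4 and Dll1 spleen mouse 2.
Values that turned sign were Dll1 in Dll1 liver (0.0496 in Cy3, 0.0701 without mouse 4), in Dll1 spleen (-0.11 without mouse 4), in the spleen difference (0.0694 in Cy3, 0.12 and 0.04 without Dll1 mouse 1 and 3, 0.07 and 0.04 without wildtype mouse 2 and 3) and between organs in Dll1 clones (0.18 without mouse 4), Sumo3 in the liver mean (0.66 with constants kept) and Coch between organs in wildtype clones (0.14 in Cy3).
Among the alternatives that left out 1 mouse, the values of Dll1 that moved farthest without turning were -0.13 in Dll1 liver without mouse 2 and 0.37 in Dll1 spleen without mouse 1. They were -0.47 in the spleen difference without wildtype mouse 4 and -0.48 between organs in Dll1 clones without mouse 1.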

Other observations

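The tests of named genes here were chosen after the result was seen.

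Beyond the genes named by rule, B2m, the light chain of MHC class I, fell by 0.30 (SE 0.05, adjusted p = 0.0479) and Tap1, a peptide transporter, fell by 0.28 (SE 0.04, adjusted p = 0.0442) in the liver mean. The MHC list had no call there by camera (adjusted p = 0.0729) or fry (adjusted p = 0.0565), with 8 of 12 members under 0. Cth, an enzyme of cysteine synthesis, fell by 0.40 (SE 0.05, adjusted p = 0.00993) and Dhx58 fell by 0.20 (SE 0.03, adjusted p = 0.0420). In the spleens of wildtype clones B2m lay at 0.45, and its difference between organs, -0.83 in wildtype clones, did not pass (adjusted p = 0.0735).

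Markers of tissue next to the spleen were measured as well. Exocrine pancreas genes had a median of 0.10 over 13 genes in the spleen mean (camera adjusted p = 0.708), with 4 members under 0 and 9 above. The list mean was 0.521 in wildtype spleen mouse 1, against -0.196 to 0.182 in the other spleens, and the cause was not tested.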
